A study of Mus musculus with 2 samples.

How the data were processed

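The series held H3K36me3 chromatin immunoprecipitation libraries from MEL cells in 2 samples of 1 group, which the labels number as biological replicates 1 and 2 of the same biosample. The deposited files were 8 peak lists in narrowPeak format on the mm10 assembly, per the labels. The deposited text files that accompany the samples derive the lists from 2 sets of processing. The first set gave a longer peak list for each replicate, a list for the pooled replicates and a larger list of replicated peaks. The second set, made from other alignments, another file taken to be the control and a further file whose role is not given, gave a pseudoreplicated list for each replicate and for the pooled replicates, and a smaller list of replicated peaks. The aligner, the peak caller, their versions and any cutoff are not given in the sources used here. Peaks were thus called by the authors both per sample and on pooled samples, and the pseudoreplicated list of each replicate was the main one here, so that each value has n = 2. The signal value of each peak was the authors', as deposited, on a scale that is not stated, and it was used only within a list, to rank, filter, describe or match peaks. The deposited −log10 p and −log10 q of each peak were also the authors', and the lowest −log10 p was 2.03 in replicate 1 and 2.05 in replicate 2. The share of peaks with a q above 0.05 was 3.44% in replicate 1 and 5.27% in replicate 2. It was higher in the other lists, from 13.3% in the longer list of replicate 1 to 40.1% in the pooled longer list. Every peak of the larger replicated list was an interval of the pooled longer list, and 81.7% of those of the smaller replicated list were intervals of the pooled pseudoreplicated list. The files held no read counts, so the depth of each library was unknown and no counting interval was given for coverage values. H3K36me3 forms broad stretches, and a caller that writes short intervals splits them, so the covered share of a gene moves with the number of peaks called.

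From the lists, the following was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Overlapping peaks were merged, and sequence outside chromosomes 1 to 19, X and Y was left out. Genes came from GENCODE mouse release M21 on the same assembly, whose chromosome lengths held every peak. Protein-coding genes of at least 500 bp were used, 21739 in all, and a symbol annotated at several places kept its longest copy. The coverage of a gene was the percent of its body, from annotated start to end, inside merged peaks, without regard to strand. A gene was called marked when at least 10% of its body was covered in each of the 2 replicates. Promoters were the 1 kb on each side of the annotated gene start. Broad domains were peaks joined over gaps of up to 3 kb and at least 20 kb long, and a domain was shared when the overlap came to at least 50% of the shorter. GC content was taken from the reference sequence. Coordinates are 1-based.

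Shares of peak bases were set against 100 placements of the list moved along each chromosome by a random circular shift, which also lets peaks fall on unsequenced gaps. The smallest p-value this allows is 0.0099. The last and first 25% of marked genes of at least 5 kb, and exons and introns of marked genes, were compared in each replicate by a two-sided permutation test of 100000 random sign flips of each gene's difference. Each of 18 gene lists was set against 10000 random lists of the same size matched on 20 bins of gene length, with a two-sided permutation p adjusted by Benjamini-Hochberg over the lists. The lists were erythroid transcription factors and receptors, haem synthesis and iron handling, globins, red cell membrane and surface, markers of myeloid, lymphoid, megakaryocyte, neuronal, hepatocyte and skeletal muscle cells, H3K36 methylation writers, erasers and readers, cell cycle and replication, cytosolic ribosomal proteins, nuclear oxidative phosphorylation subunits, Hox clusters, olfactory receptors, Zfp zinc fingers and replication-dependent histones, the last set by symbol. No gene stood in more than 1 list. All p-values are across genes or positions within these libraries and do not measure the spread between cultures.

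The genes named began with 14 fixed genes, which were Trp53 and genes of the erythroid and myeloid lineages and of the mark itself. The 10 most covered marked genes of at least 5 kb were named too. From each list came the 3 most covered members, or the single most covered member of a list with none marked. Also named were the 5 genes of at least 5 kb with the largest difference between replicates in each direction. The last were the genes under the 5 longest shared domains. This rule, the tests, the lists and the alternatives were fixed before the data were examined. The alternatives were the larger and the smaller replicated list, the pooled pseudoreplicated list, the longer list of each replicate, the stronger 50% of peaks by signal, leaving out each replicate, overlap of whole peaks by at least 1 bp or by 50% reciprocally, marked genes at 5% and at 25% of the body, only genes overlapping no other coding gene, random lists matched also on 5 bins of gene density within 500 kb, gaps of 1 kb and 5 kb, domains of at least 50 kb, and promoters of 250 bp and 2500 bp. The interval arithmetic was checked against base-by-base counts and had 0 mismatches among 5150 values. In 200 simulations on the 21739 genes, lists of 20 genes with no effect were called in 2.50%. Lists with 15 percentage points added were called in 53.5%, and lists with 30 points added in 93.0%. These calls used the unadjusted p of a single list and fewer random lists. The shares therefore do not carry over to the calls adjusted over the 18 lists, which are stricter. A lack of marked genes was not simulated. The sign-flip test over 2260 simulated genes called 4.00% with no effect and 99.5% with a shift of 0.1 SD.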

Results

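H3K36me3, the trimethylated form of lysine 36 of histone H3, was mapped by chromatin immunoprecipitation and sequencing in MEL cells, a mouse erythroleukaemia line that the labels describe as a counterpart of the human line K562. H3K36me3 is known as a mark laid down over the bodies of transcribed genes. The series held 1 group of 2 samples, numbered as biological replicates 1 and 2. The labels gave both the same biosample, and nothing said that they came from separate cultures, so the spread between them may be technical. There was no second cell type, treatment or unmarked control group, and the comparisons were therefore of the 2 replicates with each other, of the mark with gene structure, and of gene groups with random genes of matched length. The files gave no read counts, so the sequencing depth was unknown. Replicate 1 had 77634 peaks over 27.5 Mb, or 1.01% of the genome, and replicate 2 had 86592 peaks over 35.2 Mb, or 1.29%. The median peak was 283 bp wide in replicate 1 and 322 bp in replicate 2.

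The first question was how far the replicates marked the same places. The shared bases came to 12.9 Mb, which was 46.8% of the bases of replicate 1 and 36.5% of those of replicate 2, with a Jaccard index of 25.8%. When the peaks of replicate 1 were moved along each chromosome by a random circular shift, the Jaccard index averaged 0.674% and reached at most 0.820% over 100 shifts (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). Peaks of both replicates lay almost wholly inside genes, and the shifts also moved them off those genes. The shifts therefore do not test whether the replicates marked the same places within genes. Among the strongest 25% of peaks by signal, 70.3% of those of replicate 1 touched a peak of replicate 2, against 43.3% of the weakest 25%. These shares were not matched on peak width. With only the stronger 50% of peaks of each replicate, the Jaccard index was 20.3%. The replicates were also compared by gene. Across the 7537 protein-coding genes with any coverage in either replicate, the share of the gene body covered had a Spearman rho of 0.743 and a Pearson r of 0.823 between replicates. These are correlations across genes, which are not independent replicates.

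The replicates also differed at named genes. The 5 genes of at least 5 kb that were most in excess in replicate 1 were Bnip3, a mitophagy receptor, Pkm, a pyruvate kinase of glycolysis, Cenpw, Trim59 and Etaa1. Bnip3 was covered over 50.9% of its body in replicate 1 and 1.35% in replicate 2, and Pkm over 46.2% and 3.03%. Cenpw was covered over 39.95% in replicate 1 and was free of peaks in replicate 2. Trim59 was covered over 56.4% and 18.9%, and Etaa1 over 64.0% and 28.0%. The 5 genes of at least 5 kb most in excess in replicate 2 were Cyb5r1, Trib3, a pseudokinase gene induced in the integrated stress response, Akt1, Tbrg4 and Usp19. Cyb5r1 and Trib3 had no peak in replicate 1 and were covered over 65.3% and 62.9% in replicate 2. Akt1 was covered over 11.5% in replicate 1 and 63.9% in replicate 2, Tbrg4 over 17.7% and 65.6%, and Usp19 over 8.66% and 56.4%. The bases covered in replicate 1 alone had a GC content of 38.0%, and those covered in replicate 2 alone 44.2%. Among the 10% of genes with the highest GC content, 1.70% were marked in replicate 1 and 6.58% in replicate 2.

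**Figure D1:**
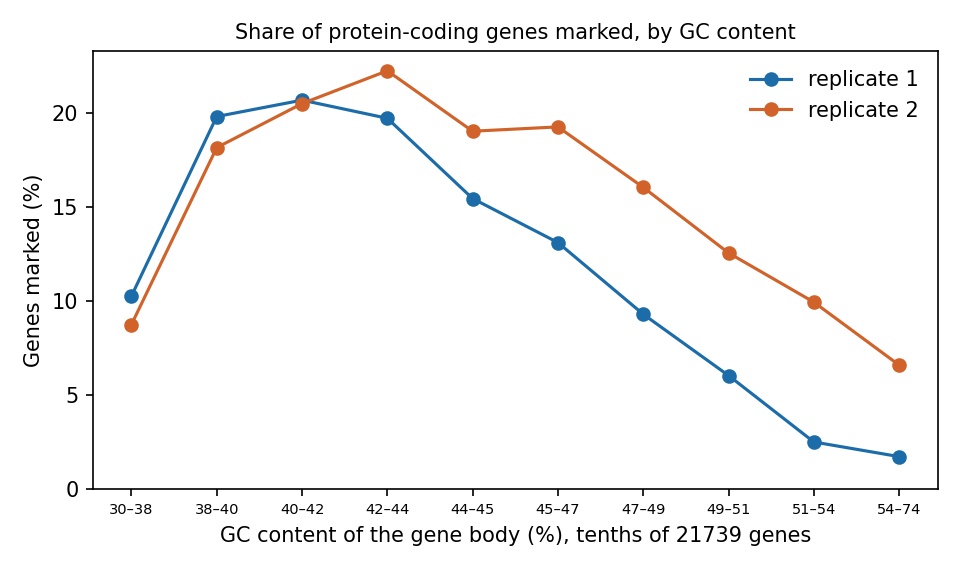
Percent of protein-coding genes marked (at least 10% of the body covered) in replicate 1 and in replicate 2 (y axis) for 10 equal bins of the 21739 genes ordered by GC content of the gene body (x axis, percent). In the bin with the lowest GC content 10.3% were marked in replicate 1 and 8.74% in replicate 2, and in the bin with the highest 1.70% and 6.58%.

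The mark lay almost wholly inside genes. Protein-coding gene bodies held 97.5% ± 0.0698 (SD, n = 2) of peak bases, while they made up 38.2% of the genome, an excess of 2.55-fold ± 0.00183 (SD, n = 2). Exons held 19.2% ± 0.665 (SD, n = 2) of peak bases against 3.52% of the genome, and introns held 78.2% ± 0.595 (SD, n = 2) against 34.6%. The region within 1 kb of an annotated transcription start held 0.202% ± 0.0207 (SD, n = 2) of peak bases against 1.505% of the genome. Bases outside any annotated gene of any kind made up 1.76% ± 0.0154 (SD, n = 2) of peak bases and 55.2% of the genome. In 100 circular shifts the genic share averaged 40.5% for replicate 1 and 40.8% for replicate 2, and the promoter share averaged 1.64% and 1.65%. No shift reached the observed genic share or fell to the observed promoter share in either replicate (one-sided permutation p = 0.0099 for each, the smaller of the 2 tails and the smallest that 100 shifts can give).

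Within marked genes, coverage was low at the 5′ end, rose to a broad maximum past the middle and was lower again at the 3′ end. In the 2163 marked genes of at least 5 kb, the first of 20 equal bins of the body was covered over 2.33% in replicate 1 and 1.32% in replicate 2. The highest value lay between 55% and 60% of the body in both replicates, at 33.6% and 39.9%, and the last bin was covered over 21.1% and 23.6%. The 5 kb upstream of these genes was covered over 1.89% and 1.74%, and the 5 kb downstream over 6.17% and 7.23%. Summed over genes, the last 25% of the body was covered over 24.8% in replicate 1 against 17.4% of the first 25%, a ratio of 1.42. In replicate 2 the values were 30.9% and 15.9%, a ratio of 1.95. The mean ratio was 1.69 ± 0.372 (SD, n = 2). Taken gene by gene, the last 25% exceeded the first by a mean of 10.3 percentage points in replicate 1 and 18.0 in replicate 2, and was the more covered in 68.7% and 79.8% of genes (two-sided sign-flip permutation p = 1e-05 in each, the smallest that 100000 resamples can give). These p-values are across genes, which are not independent replicates.

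**Figure D2:**
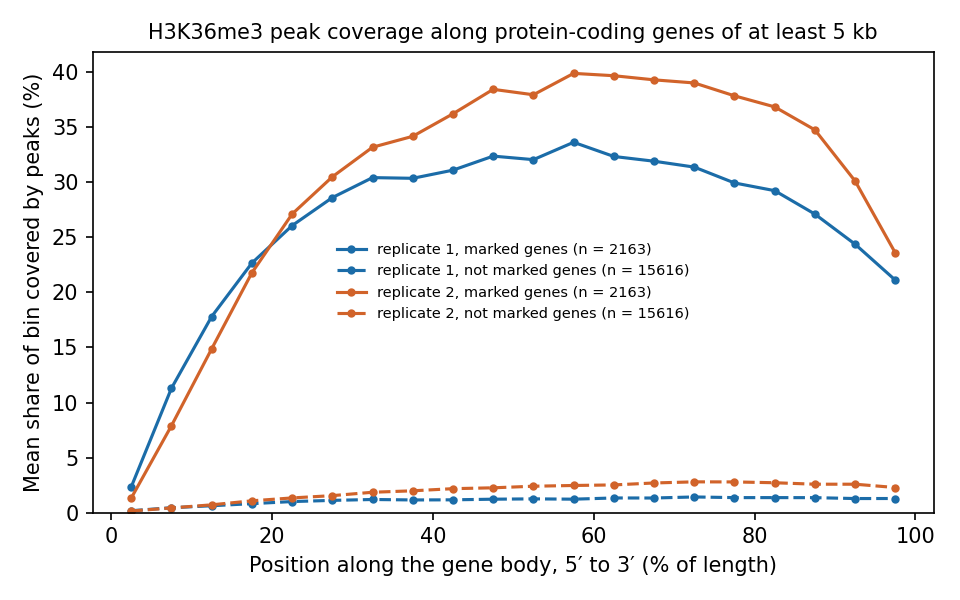
Mean percent of each of 20 equal bins of the gene body covered by peaks (y axis) from the 5′ to the 3′ end (x axis, percent of gene length), for 2163 marked genes (solid lines) and 15616 other genes (dashed lines) of at least 5 kb, in replicate 1 and replicate 2. In marked genes coverage rises from 2.33% and 1.32% in the first bin to 33.6% and 39.9% between 55% and 60% of the body.

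Exons and introns of the same genes were compared in the 2252 marked genes that have introns. Summed over genes, exonic bases were covered over 28.1% and intronic bases over 24.5% in replicate 1, a ratio of 1.15. In replicate 2 the values were 33.1% and 27.4%, a ratio of 1.21, and the mean ratio was 1.18 ± 0.0441 (SD, n = 2). Taken gene by gene, the difference in replicate 1 averaged -0.106 percentage points, with 49.7% of genes higher in exons, and it was not distinguishable from 0 (two-sided sign-flip permutation p = 0.749). In replicate 2 it averaged 1.65 percentage points, with 56.0% of genes higher in exons (two-sided sign-flip permutation p = 3e-05). The excess in exons was thus past the threshold in replicate 2 and not in replicate 1, and the difference between the replicates was not itself tested. Bases covered in replicate 2 alone had a GC content of 44.2%, against 38.0% in replicate 1 alone. The comparison of exons and introns was not matched on GC content, so an effect of GC content on it stays open. With each of the 3 pooled lists the gene-by-gene difference between exons and introns passed the threshold (two-sided sign-flip permutation p from 1e-05 to 0.00042). The ratios summed over genes there were 1.19 to 1.21. The pooled lists draw on both replicates, so they add no support independent of replicate 2. They also marked more genes, from 2876 to 3112.

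Of 21739 protein-coding genes, 2260, or 10.4%, had at least 10% of the body covered in both replicates and are called marked here. In replicate 1, 2578 genes reached this level, of which 87.7% were also marked in replicate 2, and in replicate 2, 3329 did, of which 67.9% were also marked in replicate 1. A further 14202 genes, or 65.3%, had no peak in either. Marked genes were covered over 26.3% of the body on average in replicate 1 and 30.4% in replicate 2, and 130 genes were covered over at least 50% in both. The share of genes marked was 2.62% among the shortest 20% of genes, 18.6% in the bin between 25.4 kb and 58.5 kb and 8.47% among the longest 20%. Only 8 of 1306 genes with a single exon were marked, or 0.613%, against 11.02% of genes with several exons. This contrast was not matched on gene length or gene family, so it does not show an effect of exon number. The count of marked genes depended on the list and the threshold, from 806 when 25% of the body had to be covered to 3559 with the longer peak list of each replicate.

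Among marked protein-coding genes of at least 5 kb, the most fully covered was Anln, which encodes the cytokinesis protein anillin and lies on the minus strand of chromosome 9 from 22332012 to 22389188 (mm10). It was covered over 88.7% ± 2.84 (SD, n = 2) of its body. Zfp207 on chromosome 11, which encodes a spindle-assembly protein, reached 84.2% ± 0.195, and Top2a on chromosome 11, which encodes DNA topoisomerase II alpha, reached 83.1% ± 4.90 (SD, n = 2 for each). Cep295 and Cep57, both centrosomal protein genes, were covered over 80.1% ± 1.29 and 78.6% ± 2.00. They were followed by Slc38a2, an amino acid transporter gene, at 77.1% ± 13.6 and Chordc1 at 76.6% ± 0.223. The remaining members of the 10 most covered of these genes were Eif3a, a translation initiation factor gene, at 75.1% ± 0.840, Pcbp2, an RNA-binding protein gene, at 75.04% ± 2.96, and Khdc4 at 74.6% ± 6.87 (SD, n = 2 throughout). Of these 10, 4 lay on chromosome 9 between 10 and 30 Mb, where marked genes had a median coverage of 49.3% against 24.6% elsewhere. Cep295 and Pcbp2 overlap another protein-coding gene, and peaks carry no strand, so their coverage cannot be assigned to 1 gene.

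Of the 18 gene lists fixed before the data were examined, 5 held more marked genes than length-matched random lists and 1 held fewer. Genes of the cell cycle and DNA replication were marked in 19 of 28 cases, or 67.9%, against 11.2% in the random lists. Top2a led this list, followed by Mki67, the gene of the proliferation antigen Ki-67, at 58.4% ± 1.16 and Mcm5, a subunit of the replicative helicase, at 48.7% ± 7.44 (SD, n = 2 for each). Genes of cytosolic ribosomal proteins were marked in 51 of 77 cases, or 66.2%, against 3.79% in the random lists. The most covered were Rpl31 at 60.3% ± 1.06, Rpl27 at 58.9% ± 4.22 and Rpl4 at 52.8% ± 14.5 (SD, n = 2 for each). Nuclear genes of oxidative phosphorylation subunits were marked in 29 of 84 cases, or 34.5%, against 7.55%, led by the ATP synthase genes Atp5g3 at 63.7% ± 1.10, Atp5b at 60.5% ± 17.6 and Atp5a1 at 52.2% ± 1.42 (SD, n = 2 for each). Rpl31 and Atp5a1 overlap other coding genes. The adjusted p of each of these 3 lists was 0.00045 (two-sided permutation test against 10000 random lists, Benjamini-Hochberg over the 18 lists, with an unadjusted p of 0.0001, the smallest they can give).

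Writers, erasers and readers of H3K36 methylation were marked in 10 of 26 cases, or 38.5%, against 13.7% in random lists (adjusted permutation p = 0.00432). The members most covered were Morf4l1, which encodes a chromodomain protein that binds this mark, at 46.0% ± 0.939, the Polycomb-associated gene Mtf2 at 44.5% ± 12.0 and the mismatch repair gene Msh6 at 41.5% ± 13.1. Setd2, the gene of the enzyme known to trimethylate H3K36, was covered over 29.4% ± 0.918 (SD, n = 2 for each). Mtf2 and Msh6 overlap other coding genes, and with only genes that overlap no other coding gene the excess of the list was 8.68 percentage points in place of 24.7 (adjusted permutation p = 0.437).

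Erythroid transcription factors and receptors were marked in 8 of 20 cases, or 40.0%, against 12.4% in random lists (adjusted permutation p = 0.0048). A further 7 were marked in 1 replicate only, and replicate 2 marked 15 of the 20. Myb, the gene of a transcription factor of blood progenitors, was covered over 45.7% ± 6.07, Bcl11a, a repressor of fetal globin genes, over 39.9% ± 1.597 and Ikzf1 over 28.4% ± 5.63 (SD, n = 2 for each). Epor, the erythropoietin receptor gene, was covered over 23.4% ± 6.46 (SD, n = 2). It lies on chromosome 9 between 10 and 30 Mb, a region where 23.0% of coding genes were marked, against 10.4% of all. The genes of the erythroid master regulators were covered mainly in replicate 2. Gata1 was covered over 4.64% in replicate 1 and over 15.7% in replicate 2, Tal1 over 0.861% and 16.8%, and Klf1 was free of peaks in replicate 1 and covered over 23.7% in replicate 2. The GC content was 47.6% in Gata1, 51.0% in Tal1 and 55.5% in Klf1. Across all covered genes, coverage also shifted towards replicate 2 with rising GC content (Spearman rho 0.409). A shift particular to erythroid genes is therefore not shown. Kit, the stem cell factor receptor gene, had no peak in either. The excess of this list was 8.21 percentage points with the stronger 50% of peaks (adjusted permutation p = 0.449), 5.76 when 25% of the body had to be covered (adjusted permutation p = 0.642), and 24.2 with only genes that overlap no other coding gene (adjusted permutation p = 0.0605). It was 13.8 percentage points when both lists were brought to equal covered length, an alternative chosen after seeing the data (adjusted permutation p = 0.192).

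The lists of erythroid effector genes were not distinguishable from random lists, which does not show that they lacked an excess. The haem and iron list exceeded random lists by 7.87 percentage points and the red cell membrane list by 8.50. Both lie below 15 points, the smallest excess that was simulated. For the globins, a count of 0 could not have passed the threshold. Genes of haem synthesis and iron handling were marked in 5 of 26 cases against 2.95 in random lists (adjusted permutation p = 0.344). This list passed the threshold with the larger replicated list of the series (adjusted permutation p = 0.0332) and when 5% of the body had to be covered (adjusted permutation p = 0.0455). The transferrin receptor gene Tfrc was covered over 48.2% ± 11.05, the iron-responsive regulator Ireb2 over 34.5% ± 3.92 and the ferritin light chain gene Ftl1 over 26.5% ± 17.7, while Alas2, the erythroid enzyme that opens haem synthesis, was covered over 1.32% ± 1.87 (SD, n = 2 for each). Genes of the red cell membrane and surface were marked in 4 of 18 cases against 2.47 in random lists (adjusted permutation p = 0.384). The alpha-spectrin gene Spta1, on chromosome 1 from 174172776 to 174248450 (mm10), was covered over 35.0% ± 16.6, Ermap over 20.9% ± 5.35 and the blood group gene Kel over 19.97% ± 9.10, and the glycophorin gene Gypa over 4.16% ± 5.88 (SD, n = 2 for each). None of the 7 globin genes found had a peak in either replicate, Hba-a1 and Hbb-bs among them, where length-matched random lists held 0.0605 marked genes on average (adjusted permutation p = 1). Globin genes are short and have near-identical copies, and the sources used here do not say how reads that fit several places were treated.

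No marker of another cell type was marked in both replicates, among 17 myeloid, 18 lymphoid, 13 megakaryocyte and platelet, 18 neuronal, 18 hepatocyte and 16 skeletal muscle markers. Random lists of the same lengths held 1.30, 1.79, 0.997, 1.77, 1.89 and 1.601 marked genes. Against so few, even the lowest possible count of 0 did not pass the threshold (adjusted permutation p from 0.344 to 0.664). The test could thus not detect a lack of marked genes in any single list, and the lists were not tested together. No peak at all lay on any myeloid, lymphoid, megakaryocyte or hepatocyte marker, including Adgre1, Bcl11b, Clec1b and Ahsg. Of all protein-coding genes, 65.3% had no peak in either replicate. The neuronal marker most covered was Dlg4, at 0.695% ± 0.983, and the muscle marker most covered was Ttn, at 0.150% ± 0.212 (SD, n = 2 for each). Spi1, the gene of the myeloid factor PU.1, was covered over 3.76% ± 3.16, Fli1 over 4.37% ± 1.61 and the tumour suppressor gene Trp53 over 15.4% ± 11.7 (SD, n = 2 for each), and none of these was marked in both replicates. None of the 39 Hox cluster genes was marked (adjusted permutation p = 0.344), and Hoxc9 was the most covered at 0.906% ± 1.28 (SD, n = 2). None of the 41 genes of the histone list had a peak (adjusted permutation p = 0.664), against 0.801 marked genes in random lists. That list was set by symbol for replication-dependent histones, and it also takes in H1f0, the gene of a linker histone made independently of replication, which was covered over 0%.

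**Figure D3:**
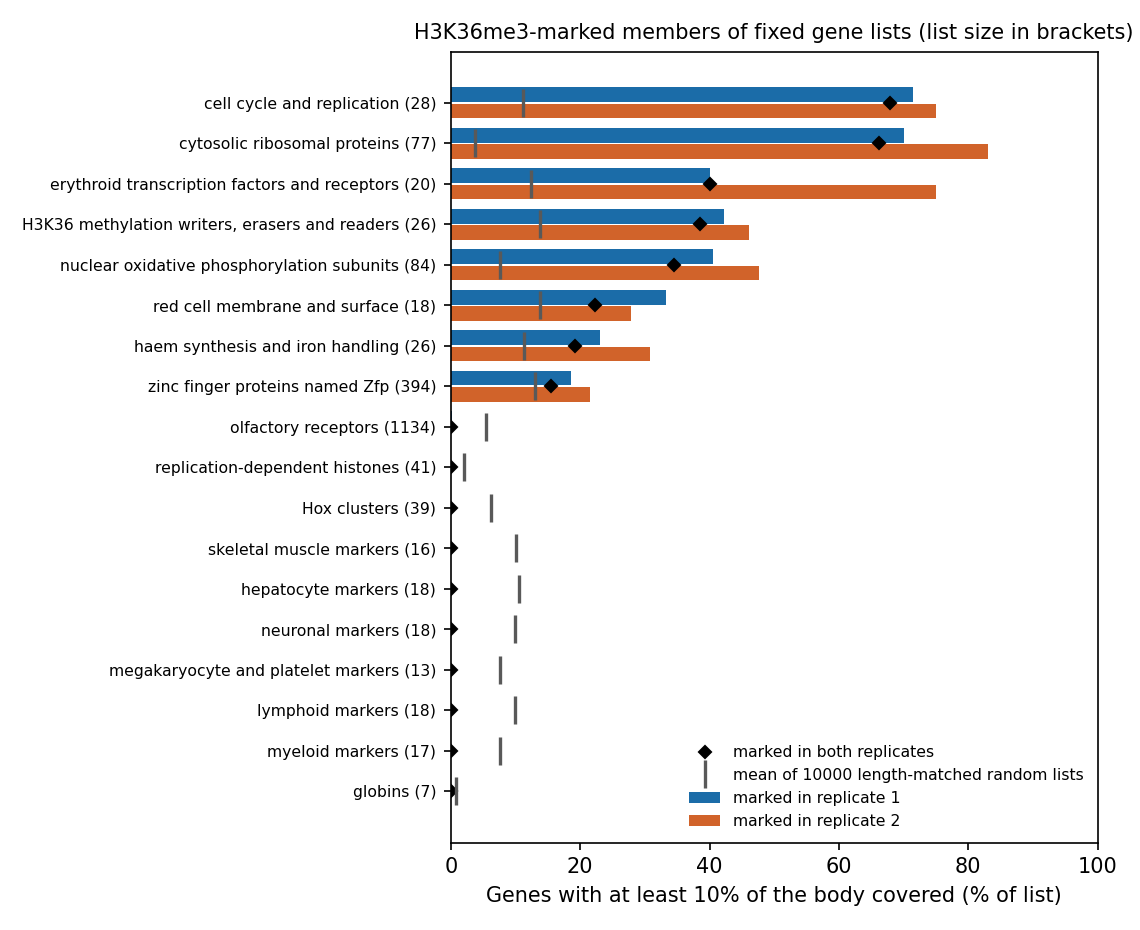
Percent of the members of each of the 18 gene lists that were marked in replicate 1 and replicate 2 (bars) and in both (diamonds), with the mean of 10000 random lists matched on gene length (vertical ticks). Cell cycle genes reach 67.9% and ribosomal protein genes 66.2% in both replicates, and the lists of other cell types lie at 0.

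Olfactory receptor genes were marked in 1 of 1134 cases, or 0.0882%, against 5.39% in random lists (adjusted permutation p = 0.00045, from the smallest unadjusted p of 0.0001). The single marked member was Olfr419, at 48.4% ± 31.1 (SD, n = 2). It lies on the minus strand of chromosome 1 from 174248514 to 174252061 (mm10), and its annotated 3′ end faces the 3′ end of Spta1 on the plus strand, which ends 64 bp before it. The next most covered members were Olfr178 at 11.5% ± 10.5 and Olfr177 at 2.01% ± 2.84 (SD, n = 2 for each). Zinc finger genes named Zfp were marked in 61 of 394 cases, or 15.5%, against 12.999% (adjusted permutation p = 0.344), and passed the threshold when 5% of the body had to be covered (adjusted permutation p = 0.0457). After Zfp207 the most covered were Zfp599 at 62.1% ± 2.75 and Zfp869 at 59.7% ± 6.65 (SD, n = 2 for each). Zfp599 lies in the region of high coverage on chromosome 9 between 10 and 30 Mb.

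**Figure D4:**
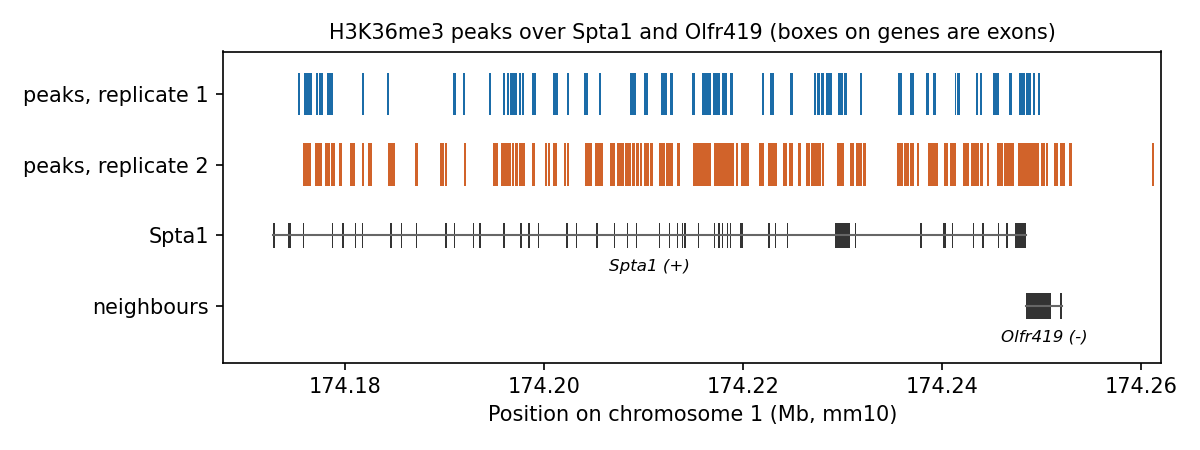
Peaks of replicate 1 and replicate 2 (coloured boxes) over Spta1 (plus strand) and Olfr419 (minus strand), with exons as dark boxes, by position on chromosome 1 in Mb (x axis, mm10). Peaks in both replicates run across the 3′ end of Spta1 into the body of Olfr419, which is covered over 26.4% in replicate 1 and 70.3% in replicate 2.

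Peaks joined over gaps of up to 3 kb formed 790 broad domains of at least 20 kb in replicate 1 and 956 in replicate 2, and 557 were shared by both. The shared domains had a median length of 27.2 kb. The longest spanned 104.2 kb of Huwe1, a ubiquitin ligase gene on chromosome X, from 151829988 to 151934207 (mm10), and peaks covered 61.5% of it in replicate 1 and 64.1% in replicate 2. The next covered Ncor1, a nuclear receptor corepressor gene, on chromosome 11 over 81.7 kb, Ubr5 on chromosome 15 over 80.6 kb, Pds5a on chromosome 5 over 79.4 kb and Bdp1 on chromosome 13 over 78.3 kb. Measured over the whole gene, Huwe1 was covered over 56.8% ± 0.344, Ubr5 over 42.5% ± 2.30, Ncor1 over 41.0% ± 1.80, Pds5a over 40.5% ± 1.40, Bdp1 over 37.4% ± 3.17 and Ttc19 over 17.5% ± 2.00 (SD, n = 2 for each). Ttc19 overlaps Ncor1, and all of its part of the domain lies inside Ncor1, so peaks there cannot be assigned to Ttc19. Of the 557 shared domains, 0 lay outside every annotated gene, which allows a share of up to 0.539%, and 556 overlapped a protein-coding gene. The number of domains depended on how peaks were joined, from 39 with gaps of up to 1 kb to 1043 with gaps of up to 5 kb.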

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

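Some peaks lay on sequence that no comparison used. Outside chromosomes 1 to 19, X and Y, the longer list of replicate 1 held 11 peaks, that of replicate 2 held 13 and the pooled longer list held 4. Each was above 3, the bound set for a closer look, which is not a measured background for these peaks. The larger replicated list held 3. The other lists, which come from another processing, held 0 and are not a measure of background here. A count of 4 is too close to 3 to set it apart. These peaks lie on sequence of the assembly that is not placed within those chromosomes, and their genes were not analysed here.

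The pooled longer list entered no comparison as a whole, although the larger replicated list, which is part of it, was used as an alternative. The pooled longer list held 28660 peaks, 21.5% of its total on the main chromosomes, that touched no pseudoreplicated peak of either replicate. Their bases lay inside protein-coding genes for 96.5%, against 38.2% of the genome, and inside the 2260 marked genes for 47.5%, against 2.88% of the genome. Their median signal was 3.15, against 3.596 for the other peaks of that list. No technical or biological explanation was tested for these values.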

How the results depend on the processing

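The alternatives matched on GC content and at equal covered length, where the weakest peaks of replicate 2 were removed until both lists covered the same length, were chosen after seeing the data. The genic share (97.0% to 97.9%), the low promoter share and the 3′ excess (ratio from 1.45 to 2.02) kept their direction and their side of the threshold under each alternative run for them, and the share of domains outside genes stayed at or below 0.0865%. Cell cycle, ribosomal protein, oxidative phosphorylation and olfactory receptor lists kept their calls in each of 13 alternatives, GC matching included. Of 234 values of single lists under alternatives, 223 kept direction and side, and 3 of lists without a call changed sign without a call: red cell membrane with the stronger peaks (-2.29 points) and at 25% of the body (-4.66), and Zfp with GC matching (-0.931).

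Whole-peak overlap, averaged over replicates, was 49.7% for at least 1 bp and 21.1% for 50% reciprocal overlap, against the Jaccard index of 25.8%. The gene-by-gene difference between exons and introns passed the threshold with the larger replicated, smaller replicated and pooled pseudoreplicated lists, which all draw on replicate 2. The summed exon to intron ratios there, which were not themselves tested, were 1.19, 1.20 and 1.21. The summed ratio ranged from 1.17 to 1.23 when 1 replicate was left out. The gene-by-gene difference passed without replicate 1 and not without replicate 2. Marked genes numbered 3559 with the longer lists, 1231 with the stronger 50% of peaks and 806 at 25% of the body, against 2260. The erythroid factor list lost its call with the stronger peaks (8.21 points), at 25% (5.76), with genes overlapping no other coding gene (24.2) and at equal covered length (13.8). The H3K36 methylation list lost its call with genes overlapping no other coding gene (8.68). The haem and iron list passed with the larger replicated list (18.9) and at 5% (17.9), and the Zfp list at 5% (4.54). Broad domains numbered 1156, 901 and 1051 in the larger replicated, smaller replicated and pooled pseudoreplicated lists and from 790 to 956 with 1 replicate left out, single lists in which sharing could not be required. Domains shared by both replicates, 557 in the report, numbered 1366 with the longer lists, 107 with the stronger peaks, 39 and 1043 with gaps of 1 kb and 5 kb, and 60 at 50 kb or more. The rank correlation was 0.829 with the longer lists, 0.619 with the stronger peaks and 0.710 at equal covered length. Counts fall by construction where fewer bases are called or a stricter bound is set. For the other changes the cause was not tested. Read depth is unknown, so the lack of a peak over a gene does not show that the mark is absent there.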

Other observations

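Tests of symbol families, non-coding genes and genes on chromosome Y, and the patterns weighed here, were chosen after the data were seen. Predictions were written before the tests of the weighed patterns, except that the ATF4 and CHOP targets had none, and the permuted maps for chromosome 9 were added after matched random sets had been seen. Genes were grouped by the letters that open their symbol, and the 360 families of at least 8 genes were set against length-matched random lists. After adjustment 23 held more marked genes than expected and 5 fewer. The splicing factor family Srsf was marked in 9 of 11 cases against 1.00 expected, the nuclear pore family Nup in 16 of 21 against 3.28, the splicing family Prpf in 9 of 13 against 2.06, and the proteasome family Psmd in 9 of 14 against 1.64. Translation initiation genes (Eif) were marked in 32 of 55 cases against 6.81, the RNA helicase family Ddx in 20 of 37 against 5.20, and the RNA-binding family Rbm in 20 of 39 against 4.42 (adjusted permutation p = 0.00257 for each, from the smallest unadjusted p of 0.0001). Cytochrome P450 genes (Cyp) were marked in 0 of 100 cases against 13.8 expected (adjusted permutation p = 0.0045), vomeronasal receptor genes (Vmn) in 0 of 330 against 33.3, and solute carriers (Slc) in 18 of 371 against 49.7 (adjusted permutation p = 0.00257 for both).

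Of 6980 non-coding genes that overlap no protein-coding gene, 21 were marked in both replicates. Mir17hg, the host gene of the miR-17 microRNA cluster on chromosome 14, was covered over 97.5% in replicate 1 and 100% in replicate 2, and its nearest coding gene lay 45487 bp away. Small nucleolar RNA host genes named Snhg made up 5 of the 21, led by Snhg1 at 66.2% and 67.7%, which lies 105 bp from its nearest coding gene, so that its coverage cannot be set apart from that gene's. The 1 shared broad domain outside coding genes lay over Pvt1 on chromosome 15 from 62225071 to 62251374 (mm10), 26.3 kb long. On chromosome Y, 3 genes were marked in both replicates, Ddx3y at 56.7% and 51.3%, Eif2s3y at 43.1% and 35.95%, and Uty at 20.1% and 15.5%.

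Genes of the hypoxia response and glycolysis were more covered in replicate 1, and genes known as targets of the stress factors ATF4 and CHOP in replicate 2. The 2 lists were written after Bnip3, P4ha1, Pkm and Trib3 had been seen to differ. Of 27 hypoxia and glycolysis genes with any coverage that had not been seen before, 22 were more covered in replicate 1, with a mean of 18.0% against 9.63%, Pgk1 (40.9% and 8.51%), Kdm3a (66.3% and 34.0%) and Higd1a (33.8% and 7.06%) among them. Their mean difference lay further towards replicate 1 than in 100% of 10000 random lists matched on GC content and mean coverage, which argues against a GC trend, since lists matched to the 27 lay 6.92 points towards replicate 2. Of 18 covered ATF4 and CHOP targets not seen before, 1 was more covered in replicate 1, with means of 13.7% and 33.5%. Atf4 (0% and 50.7%) and Nars (26.5% and 59.7%) were among the 18. Their mean difference was 19.8 points towards replicate 2, where matched lists already lay 11.4 points that way on average. Only 0.03% of matched lists lay further towards replicate 2. A difference in the state of the cells between the replicates is a candidate explanation, but the labels give no culture conditions, and a difference between library batches stays untested.

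Genes marked in 1 replicate only numbered 318 in replicate 1 and 1069 in replicate 2, with mean GC contents of 42.7% ± 4.43 and 48.1% ± 4.55 (SD over genes). Across the 7537 covered genes, the coverage difference, replicate 2 minus replicate 1, rose with gene GC content (Spearman rho 0.409, across genes, which are not independent replicates), consistent with libraries that read GC content differently. A larger covered length of replicate 2 as the whole cause is argued against, since 67.1% of the genes marked only there stayed marked after its weakest peaks were removed down to the length of replicate 1. At that length 717 genes were marked only in replicate 2 and 561 only in replicate 1, and rho was 0.436. A real difference between the cells that follows GC content stays open, as in the lists above.

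Marked genes on chromosome 9 between 10 and 30 Mb, a region picked for its high coverage, had a median coverage of 49.3% over 40 genes, against 24.6% elsewhere, and the highest window of 20 Mb began at 0 Mb of that chromosome, at 55.6%. They had a median of 32.5 neighbours within 500 kb against 14 elsewhere, as gene density would need. Coverage was then permuted among marked genes of like density, in 5 bins, and like length. In 99.59% of 10000 such maps, every window of 20 Mb with at least 10 marked genes lay below 49.3%. That argues against density as the whole cause, as far as 5 bins match it. The permutation also separates neighbouring genes, so it does not tell what else makes them alike. More copies of the region in the cells may account for its high coverage, as extra copies add reads to sample and control alike. At matched signal, the median −log10 p of its peaks stood 2.35 above that of like peaks in replicate 1 and 2.49 in replicate 2, higher than in 100% of 140 other windows of 20 Mb in both. Those windows left out the first 40 Mb of chromosome 9, which holds the region and the highest window, and any window with few peaks. The same prediction put chromosome X below the median window, but that part was uninformative, since 108 of the 140 windows in replicate 1 and 114 in replicate 2 lay at 0, as X did, so the copy number explanation stays open, as does GC content (median 46.3% against 42.7% elsewhere), which was not tested.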
